A study of Mus musculus with 12 samples.

How the data were processed

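The series examined N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA that FTO can remove, in mouse hippocampus. The labels describe 12 samples. Deposited lists of m6A-enriched regions were analysed for 4 of them: 2 immunoprecipitated (m6A-IP) libraries from 2-week-old and 2 from 6-week-old wild-type males. In m6A-IP, fragmented poly(A)+ RNA is pulled down with an antibody against m6A and sequenced, and regions with more sequence tags than in a control of unselected fragments (the input) are called as peaks. The other 8 samples, among them the hippocampal RNA-seq of adult Fto knockout and wild-type mice aged 8 to 12 weeks, were not analysed here. The labels number the libraries of each age as biological replicates 1 and 2, without naming the animals, so p-values of the tag comparisons measure the spread between these samples. P-values from counts or permutations of regions or loci do not measure that spread.

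The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.13 and 2.1.1, Cufflinks 2.2.1, HOMER without a version, and the mouse build mm9, with no role or order. The column names in the files are those of HOMER's peak caller. Each library has its own list, so peaks were called per library and replicates were not pooled. The caller's options and the input library that served as each control are not given in the sources used here. In every deposited list the fold over control was at least 3 and the p-value against control was at most 8.32e-05. The deposited normalized tag count is a signal scaled by 1 constant per library. The deposited list of 2-week replicate 1 gives IP tags as whole counts and control tags scaled to the IP depth, and the other lists give scaled IP tags and unscaled control tags. The deposited score, the fold ratio over control and the p-value of each peak are the authors' values and were used only to describe, rank or filter peaks within a list. The deposited focus ratio, a fraction, was read but not used. All peaks carried the same strand sign, so strand was ignored.

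Whole tags were recovered by dividing scaled columns by the value of 1 tag. IP values came out whole, within 0.2 tag, for 100.0% of peaks in each list, and control values for at least 99.99%. A control value worth 0.5 tag stood for no control tag and was set to 0. If the deposited signal was scaled to 10000000 tags, HOMER's default, the IP libraries held 23.4, 23.0, 16.1 and 16.5 M tags (M, mega; 2-week replicates 1 and 2, then 6-week replicates 1 and 2) and the controls 29.3, 16.8, 15.8 and 11.7 M. The 2-week IP libraries were therefore the deeper ones, and depth and age cannot be separated by design. Some peaks (1.92%, 2.00%, 2.69% and 1.97% of the lists) repeated the printed start of an earlier peak, the first peak at each start not counted. Where the tag numbers of such peaks differed, the tags were not all counted over the printed interval.

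Overlap was the share of peaks of one list that shared at least 1 bp with a peak of the other, taken both ways and averaged. As a background, 1 list of each pair was shifted by 1000 bp up and down. The share of the other list's peaks that overlapped it was averaged over both shifts, in 1 direction only. The within-age minus between-age difference was tested by exact permutation over the 3 ways to split 4 libraries into pairs, which cannot give a p under 0.333. Peaks of all lists sharing at least 1 bp were merged into regions. A region called at one age only was called in both libraries of that age and in neither of the other. Regions less than 10000 bp apart were joined into loci. Tags were compared only at the 4577 regions with exactly 1 peak in each list. Each library's tags were those of its own peak, and peak starts lay within 20 bp of each other in 1435 of these regions. The IP enrichment test was the interaction of fraction (IP or input) and age in edgeR's quasi-likelihood fit with a sample term, and the input test compared 6 with 2 weeks in the control tags with an offset for peak width. Both used TMM scaling and Benjamini-Hochberg adjustment with a threshold of 0.05. The same fit of the IP tags alone was added after the data were seen. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The replicate libraries differed by more than sampling noise in the jointly called regions, with chi-square per degree of freedom of 16.7 and 22.0 in IP tags and 3.17 and 2.55 in control tags at 2 and 6 weeks.

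The fits were tested on simulated tags for the 4577 regions, with 50 regions changed at each size. The tags were drawn with a single fixed dispersion (spread beyond sampling noise) for all regions, and IP independently of input. The real fits estimated a common dispersion of 0.0309 for enrichment and 0.0545 for input, so rates in the real data may differ. The enrichment fit recovered 6% at a log2 change of 1, 34% at 2 and 58% at 3, with 2 false calls. The input fit recovered 12% at 1, 62% at 2 and 90% at 3, with 3 false calls.

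Coordinates are those of the files (mm9). The gene table at hand is on another build, and coordinates were not converted, so regions are named by position and no gene, exon or UTR is given. Gene lists fixed before the data were examined were not tested for the same reason. Named regions followed a rule also fixed then: up to 12 per direction with the smallest p among those past the threshold of a fit, or, if none passed, 5 per direction said not to have passed, and up to 10 per age among regions called at one age only, ranked by the lower of both score percentiles, of which the first 5 per age are described. The alternatives were stricter peaks (at least 8-fold), other overlap rules, equal list lengths, merging within 200 bp, total-tag scaling, DESeq2, limma, a tag filter, other model terms and leaving out each library. Removing the mitochondrial and Y chromosomes, thinning to equal depth, a margin over the thresholds, limma for the input tags and requiring peak starts within 20 bp were added after the data were seen.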

Results

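The data were lists of m6A peaks from the hippocampus of wild-type mice at 2 and 6 weeks of age, with 2 libraries per age. The lists held 39259 and 39105 peaks at 2 weeks and 33239 and 36494 peaks at 6 weeks, nearly all 100 bp wide. Median enrichment over control was 5.97-fold and 7.33-fold at 2 weeks and 6.20-fold and 6.38-fold at 6 weeks. Peaks held 21.7% and 24.4% of all IP tags at 2 weeks and 22.2% and 16.0% at 6 weeks. IP depth, taken from the scaling of the files, was 23.4 and 23.0 M tags at 2 weeks and 16.1 and 16.5 M at 6 weeks. With 2 libraries against 2, no exact two-sided test of these values can give a p under 0.333.

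The first question was how far the m6A map is shared between the ages. The 2-week replicates shared 61.5% of their peaks, the mean of both directions, and the 6-week replicates 47.1%. Pairs of libraries of different age shared 47.8% to 51.0%, with a mean of 49.9% ± 1.49 (SD over 4 pairs). The 6-week replicates thus overlapped each other less than the ages overlapped on average. After a shift of 1000 bp, 5.80% to 7.52% of peaks still overlapped, counted in 1 direction only. The within-age mean was 54.3%, which is 4.35 percentage points above the between-age mean. The exact one-sided permutation p was 0.333, the smallest that the 3 splits of 4 libraries allow. In base pairs, the 2-week replicates shared 30.1% of their combined length, the 6-week replicates 19.8%, and pairs of different age 20.5% to 23.2%.

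**Figure D1:**
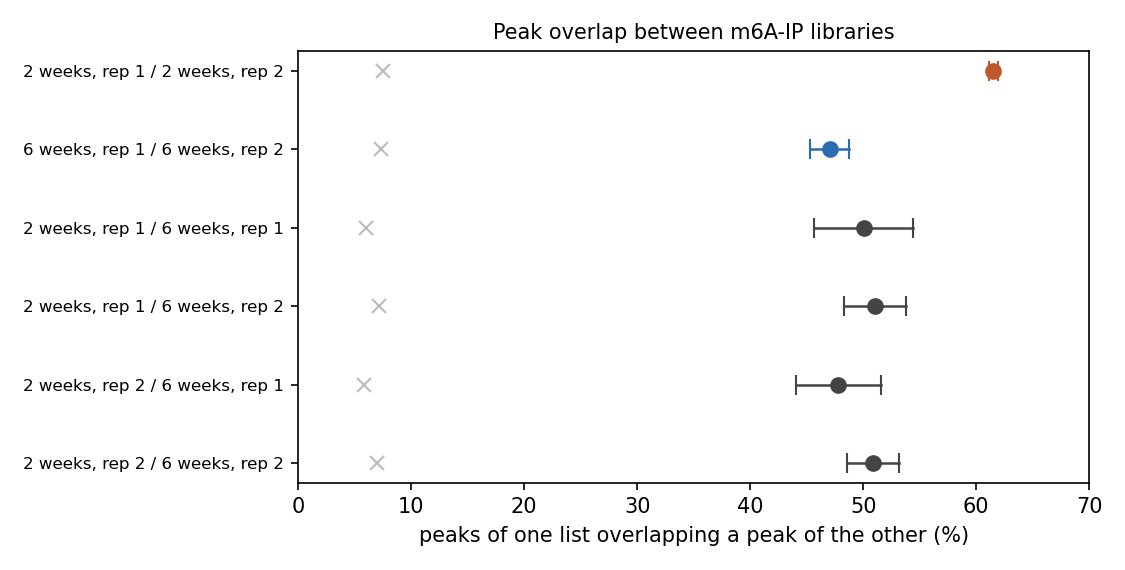
Share of peaks of one library that overlap a peak of another by at least 1 bp, in percent, for the 6 pairs of the 4 m6A-IP libraries. Dots are the mean of both directions, and bars end at the value of each direction. Crosses are the overlap after a shift of 1000 bp, in 1 direction only. The 2-week pair stands at 61.5% and the 6-week pair at 47.1%.

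The next comparison asked which regions were called at one age only. The lists merged into 70674 regions, of which 10203 were called in all 4 libraries and 41449 (58.6%) in a single library. At 2 weeks only, 4527 regions were called, and at 6 weeks only, 1359, a ratio of 3.33. These 5886 regions compare with 3196 for the split of replicates 1 against replicates 2 and 2489 for the crossed split. Regions called at one age only held fewer IP tags than shared ones: their median was 19 and 21 tags in the 2-week libraries and 35 and 27 in the 6-week libraries, against 139, 151, 89 and 60 in regions called in all 4. Their median fold over control was 6.46 and 8.06 in the 2-week libraries, against 6.54 and 6.52 in regions called in all 4, and 4.57 and 5.08 in the 6-week libraries, against 8.28 and 6.03. When the tags of all libraries were thinned to the same depth, a setting added after the data were seen, the counts were 2141 and 1550 (medians of 20 draws), a ratio of 1.38. At that depth the regions of both ages numbered 3686, against 2868 for the split of replicates 1 against replicates 2 and 2233 for the crossed split (medians). Thinning can remove peaks but not add them. With 6-week replicate 1 left out the counts were 6999 and 12728, and without 6-week replicate 2 they were 7595 and 12370, since 1 list then needs no second call; without 2-week replicates 1 and 2 they were 14782 and 2614, and 14275 and 2266.

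**Figure D2:**
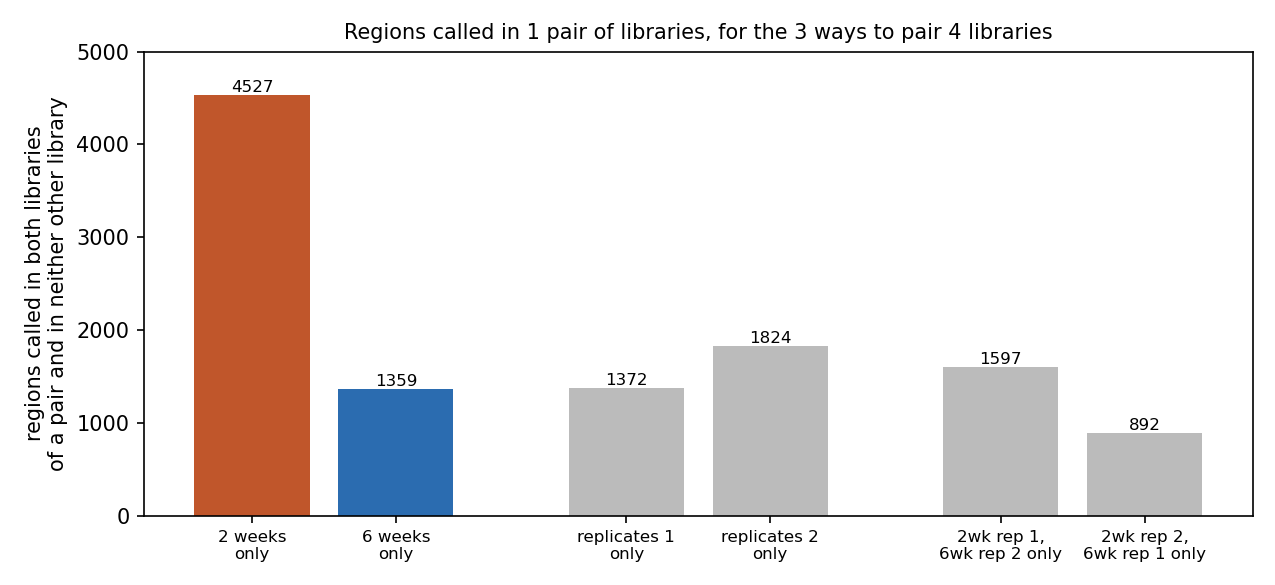
Number of regions called in both libraries of a pair and in neither of the others, for the 3 ways to pair the 4 libraries. The 2-week pair holds 4527 regions and the 6-week pair 1359, while pairs that mix the ages hold 892 to 1824.

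Among regions called at 2 weeks only, the highest in score was chromosome 17 from 45707355 to 45707465 (mm9), with 11282 and 21449 IP tags in replicates 1 and 2 at 3.14-fold and 4.10-fold over control. It was followed by chromosome 8 from 87366539 to 87366698, at 3.10-fold and 3.37-fold, chromosome 18 from 61144547 to 61144671, at 4.43-fold and 4.62-fold, chromosome 12 from 30496449 to 30496549, at 3.17-fold and 3.88-fold, and chromosome 15 from 25293954 to 25294062, at 4.54-fold and 3.01-fold. The folds of these 5 regions ranged from 3.01 to 4.62, where the lists start at 3. The region on chromosome 15 lay 73 and 72 bp from the nearest peaks of the 6-week libraries, and that on chromosome 18 lay 238 and 206 bp away. The distances were 3131 and 3142 bp on chromosome 17, 3950 and 7858 bp on chromosome 8, and 15492 and 15178 bp on chromosome 12. At 6 weeks only, the highest was chromosome 3 from 88879990 to 88880093, with 411 and 357 IP tags at 4.62-fold and 3.05-fold, and peaks of the 2-week libraries 8774 and 15476 bp away. Next came chromosome 4 from 137762133 to 137762235, at 3.28-fold and 3.31-fold, chromosome 12 from 60173519 to 60173764, at 4.08-fold and 3.12-fold, chromosome 14 from 55726243 to 55726369, at 3.55-fold and 3.08-fold, and chromosome 6 from 72103587 to 72103802, at 3.53-fold and 5.32-fold. The last of these lay 49 and 50 bp from the nearest 2-week peaks. The distances were 9861 and 486 bp on chromosome 4, 825 and 813 bp on chromosome 12, and 8473 and 8931 bp on chromosome 14. No test was run per region, since an exact two-sided test of 2 calls against 2 cannot give a p under 0.333.

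Some loci held several regions called at one age only; whether such regions cluster more than peaks in general was not tested. On chromosome 8, 10.3 kb from 124785151 to 124795425 held 10 regions called at 2 weeks only and none called at 6 weeks only; the lists had 24 and 16 peaks there at 2 weeks, 1 in 6-week replicate 1 and 0 in 6-week replicate 2. On chromosome 18, from 37090412 to 37135356, 9 regions were called at 2 weeks only beside 5 called in all 4 libraries. At 6 weeks, chromosome 16 from 5049448 to 5089290 held 5 regions called at that age only and 3 called in all 4 libraries, and chromosome 7 from 71517711 to 71537590 held 4. The 2-week loci with the most regions called at that age only were chromosome 11 from 3000465 to 3080307 with 17 and chromosome Y from 2850272 to 2902498 with 12. These loci held 69 and 126 regions in all, of which 2 and 0 were called in all 4 libraries. Peaks on chromosome Y numbered 276 and 132 in the 2-week lists and 17 and 89 in the 6-week lists. Over the genome, 164 loci had at least 3 regions called at 2 weeks only and none called at 6 weeks only, and 9 loci the reverse. These counts start from 4527 regions called at 2 weeks only and 1359 at 6 weeks only, in lists from deeper 2-week libraries. Needing at least 3 of a kind widens such an imbalance, and the counts expected from it were not computed. Among loci with 1 kind only, no chromosome passed a test of its balance of 2-week to 6-week loci against the rest of the genome after Benjamini-Hochberg adjustment (Fisher's exact test, 22 chromosomes, lowest adjusted p = 0.0911 on chromosome 2).

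**Figure D3:**
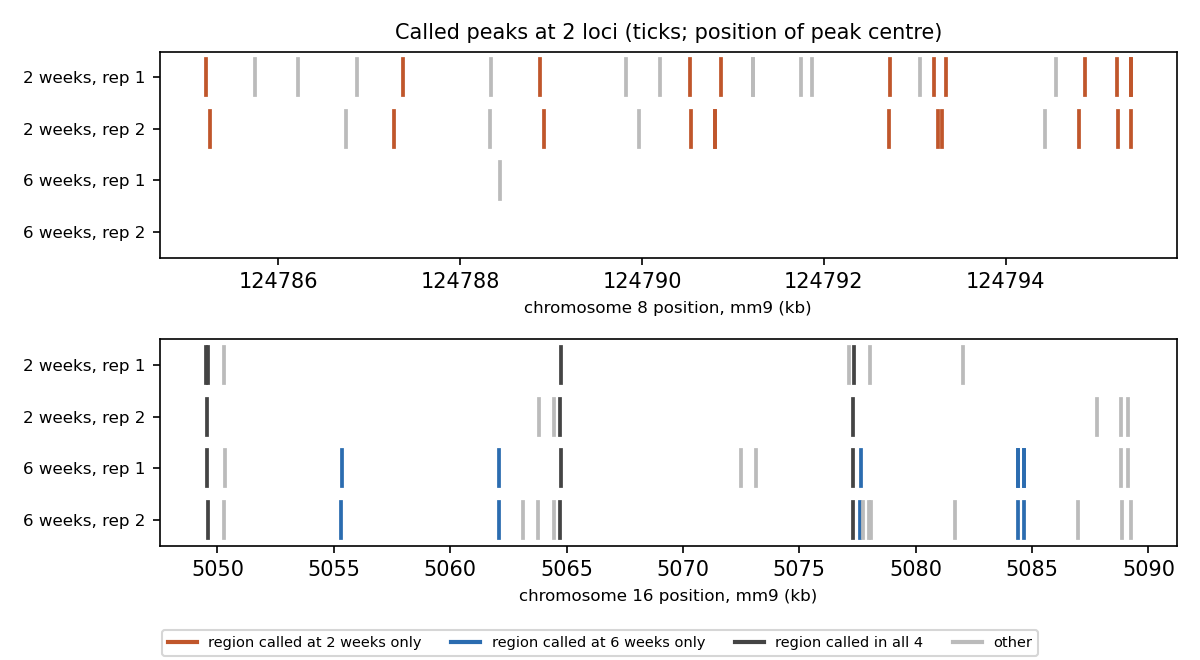
Called peaks in each of the 4 libraries, as ticks at the peak centre, along chromosome 8 from 124785151 to 124795425 and chromosome 16 from 5049448 to 5089290 (mm9, position in kb). Colours mark regions called at 2 weeks only, at 6 weeks only, in all 4 libraries or otherwise; the first locus has 24 and 16 peaks at 2 weeks and 1 and 0 at 6 weeks.

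At the 4577 regions with exactly 1 peak in each list, RNA level and enrichment were compared between the ages separately. Each had passed a 3-fold minimum in every list, so regions whose enrichment fell below it at 1 age were left out. Input tags, a measure of poly(A)+ RNA in the peak, rose from 2 to 6 weeks in 51 of 4577 regions and fell in 49, relative to the median region. They were counted in each library's own peak, so a shift of the peak between libraries can also move them. The smallest p among those that rose was at chromosome 19 from 5802514 to 5802640, with 40.6 ± 11.5 input tags per 10 M at 2 weeks and 141 ± 27.0 at 6 weeks (SD, n = 2 each), a log2 change of 2.34 ± 0.34 (SE; edgeR adjusted p = 1.82e-06). A second region on that chromosome, from 5843904 to 5844043, rose by a log2 of 2.61 ± 0.42. Chromosome 2 held a pair of rising regions, from 156347539 to 156347706 and from 156347838 to 156347963, with log2 changes of 3.39 ± 0.61 and 3.03 ± 0.46. Chromosome 9 also held a pair, from 111269385 to 111269505 and from 111294360 to 111294466, with 1.89 ± 0.39 and 2.12 ± 0.33. Chromosome 6 from 135683553 to 135683679 rose by 2.87 ± 0.44 and chromosome 15 from 74502176 to 74502297 by 2.06 ± 0.36. The change was 4.24 ± 0.76 at chromosome 16 from 5183896 to 5184085 and 3.95 ± 0.71 at chromosome 11 from 74986741 to 74986956, where the 2-week controls held 2 and 1 tags and 2 and 2 tags. Peak starts of the libraries lay up to 89 and 115 bp apart at these regions, and up to 67 bp apart at chromosome 2 from 156347539. At chromosome 9 from 89854898 to 89855059 the 2-week controls differed, with 4 and 52 tags, and the log2 change was 2.33 ± 0.46; it was 1.31 without 2-week replicate 1 and 5.55 without 2-week replicate 2, neither past the threshold, and DESeq2 did not call it. At chromosome 15 from 79748072 to 79748268 it was 1.99 ± 0.45, and 1.54 and not past the threshold without 6-week replicate 2. DESeq2 gave no adjusted p for 3 of these 12 regions, those on chromosomes 16 and 11 and chromosome 2 from 156347539.

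The smallest p among regions whose input tags fell was at chromosome 10 from 43302772 to 43302887, with 25.6 ± 7.67 tags per 10 M at 2 weeks and 2.01 ± 1.64 at 6 weeks (SD, n = 2 each), a log2 change of -3.07 ± 0.59 (SE; edgeR adjusted p = 0.000405). The change was -2.70 ± 0.52 at chromosome 18 from 63111796 to 63111954 and -1.67 ± 0.40 at chromosome 18 from 42805412 to 42805522. On chromosome 9 it was -2.11 ± 0.42 from 21820602 to 21820725 and -1.99 ± 0.42 from 20472851 to 20473003. On chromosome 13 it was -1.80 ± 0.42 from 51519897 to 51520028 and -1.34 ± 0.32 from 34220235 to 34220351, the latter -1.23 and not past the threshold without 6-week replicate 2. On chromosome 5 it was -1.85 ± 0.38 from 143040543 to 143040692 and -1.92 ± 0.47 from 75591267 to 75591385. The remaining named regions were chromosome 6 from 54456027 to 54456149 at -2.07 ± 0.42, chromosome 11 from 51935504 to 51935625 at -1.52 ± 0.34 and chromosome 15 from 77822428 to 77822568 at -2.33 ± 0.54. DESeq2 did not call chromosome 5 from 75591267, and gave no adjusted p for chromosome 10, chromosome 18 from 63111796 and chromosome 15.

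The balance of rises and falls depended on the scaling. With total tags in place of TMM, 21 regions rose and 370 fell, and the median region moved from a log2 change of -0.03 to -0.53. Per 10 M tags, without TMM, both 6-week controls lay below both 2-week controls in 2199 of the 4577 regions and above both in 315. The jointly called regions held 1.07% and 1.26% of all control tags at 2 weeks and 0.854% and 0.774% at 6 weeks. DESeq2, which gave no adjusted p for 3106 regions, called 22 and 13, and limma called 2 and 0, with 605 at an unadjusted p under 0.05. No region was called by edgeR when 2-week replicate 1 was left out (285 at an unadjusted p under 0.05) or 2-week replicate 2 (372), while leaving out 6-week replicate 1 gave 85 and 72.

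In all 100 regions with an input change, the fitted, TMM-scaled change of the IP tags had the same sign. Per 10 M tags, without TMM, both 6-week IP libraries lay above both 2-week ones in 32 of the 51 regions whose input rose and below both in 1, and below both in all 49 whose input fell; over all 4577 regions they lay below both in 1977 and above both in 297. Among the 100 regions with an input change, the median size of the log2 change was 1.82 in input, 1.33 in IP and 0.44 in the ratio of IP to input. These regions were selected on their input change, which favours a large value in input over the other measures. Across the 4577 regions the log2 changes of input and IP tags correlated with a Pearson r of 0.614; regions are not independent replicates, and each had passed a 3-fold minimum in every list, which ties both values together. Tested alone, IP tags rose in 39 regions and fell in 11, of which 12 and 5 were also called in the input; DESeq2 called 60 and 44, and total-tag scaling gave 0 IP calls in edgeR (736 at an unadjusted p under 0.05). Leaving out 2-week replicate 1 or 2 gave 6 and 4 IP calls. Without 6-week replicate 1, 167 rose and 126 fell, and without 6-week replicate 2, 402 rose and 325 fell.

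**Figure D4:**
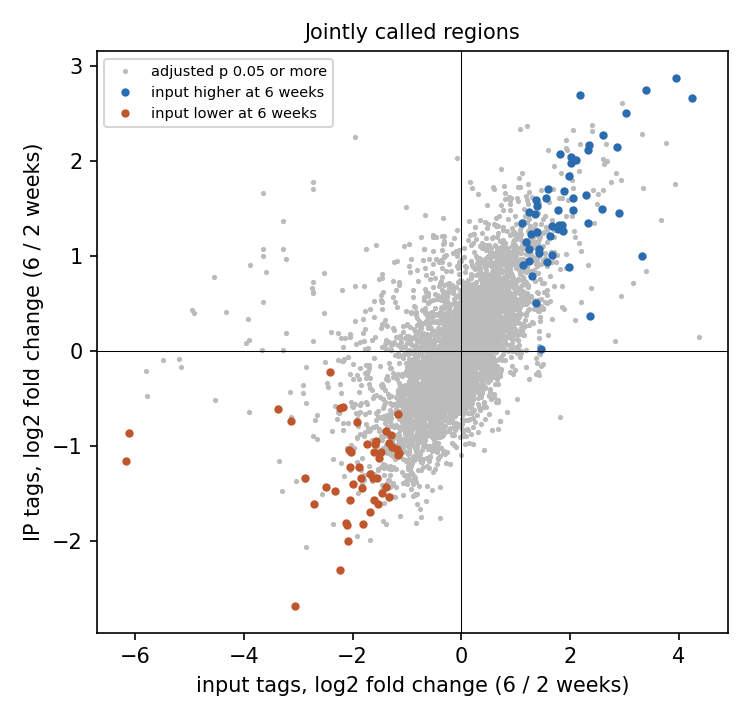
Log2 fold change from 2 to 6 weeks of IP tags (vertical) against input tags (horizontal) in the 4577 jointly called regions, TMM-scaled, 2 libraries per age. Blue and orange points are the 51 regions whose input rose and the 49 whose input fell by edgeR, and in all 100 the fitted IP change has the same sign; with total-tag scaling the input counts are 21 and 370.

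The last comparison asked whether m6A enrichment, the IP to input ratio, differed between the ages at these regions. Regions that fell below the 3-fold minimum at 1 age were not among them, so the result says nothing about those. The scaling centred the regions near no change (median log2 change 0.02 in edgeR). A change of the ratio shared by most regions could therefore not be seen, only changes relative to the typical region. No region passed the threshold in edgeR, with 127 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999. DESeq2 and limma also called 0, with 28 and 138 at an unadjusted p under 0.05. The counts of 127, 28 and 138 are each below what evenly spread p-values would give. The regions with the smallest p toward higher enrichment at 6 weeks, none of which passed, were chromosome 2 from 32453076 to 32453186 (log2 change 2.17 ± 0.69, SE), chromosome 8 from 124360293 to 124360403 (2.77 ± 0.89), chromosome 6 from 118379013 to 118379173 (2.79 ± 0.90), chromosome 6 from 6988859 to 6988997 (2.93 ± 0.95) and chromosome 8 from 126521843 to 126521949 (2.19 ± 0.72). Their 6-week controls held between 0 and 6 tags. Where the only 6-week control left held 0 tags, the fitted value went to 8.36 on chromosome 2 (without 6-week replicate 1) and 8.35 at chromosome 6 from 118379013 (without 6-week replicate 2), neither of which is a bound on the change. Toward lower enrichment they were chromosome 5 from 126267606 to 126267722 (-1.47 ± 0.41), chromosome 3 from 107133221 to 107133382 (-2.0 ± 0.65), chromosome 12 from 109149312 to 109149434 (-1.51 ± 0.50), chromosome 18 from 62656239 to 62656360 (-2.47 ± 0.83) and chromosome 12 from 47801530 to 47801645 (-1.46 ± 0.53); the value on chromosome 18 was -0.95 without 6-week replicate 1. The median SE over all regions was 0.53, and on simulated data the fit recovered 34% of regions changed by a log2 of 2. Without 6-week replicate 2, 2 regions passed toward higher enrichment.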

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

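Settings with peaks thinned, with a margin over the thresholds, without the mitochondrial and Y chromosomes, with starts within 20 bp, limma on input tags and the IP fit were chosen after the data were seen. At 8-fold or more, the lists held 13196, 17225, 12539 and 12873 peaks, the overlap difference was 2.71 percentage points, and 1788 and 767 regions were called at 2 and 6 weeks only; fewer peaks enter by construction. Thinning gave 2140.5 regions at 2 weeks (median), and the margin 248 and 89. Leaving out 1 library gave 6999 to 14782 regions at 2 weeks only and 2266 to 12728 at 6 weeks only, since a single list then needs no second call: without 6-week replicate 1 the counts were 6999 and 12728, without 6-week replicate 2, 7595 and 12370. Other overlap rules, equal list lengths, merging within 200 bp and removing the mitochondrial and Y chromosomes kept these counts within 1.5 times.

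Input calls (51 higher, 49 lower) became 21 and 370 with total tags, 22 and 13 with DESeq2 (33 of its 35 calls among the 100), 2 and 0 with limma, and 14 and 14 with starts within 20 bp, where fewer regions were tested. Leaving out 1 library gave 0 to 85 higher and 0 to 72 lower, with 0 without either 2-week replicate; the lone library is then assumed to vary like the other age. The width offset moved nothing. Enrichment calls stayed at 0 in all settings but 1: leaving out 1 library gave 0 to 2. IP calls (50) were 0 with total tags, 104 with DESeq2, 22 with starts within 20 bp and 4 to 727 with 1 library left out (the extremes without replicate 2 of 2 and of 6 weeks). Besides the changes in input calls, total tags moved the median enrichment change from 0.02 to 0.15. The causes were not tested. No region named from the input or enrichment fits changed direction. The named regions called at one age only were not followed through these settings.

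Across the jointly called regions the replicate numbers did not pair the libraries: deviations from the age mean correlated by 0.03 (IP) and 0.05 (input). Other values went with the number. Mitochondrial peaks held 416 and 463 IP tags per M in replicates 1 of 2 and 6 weeks, and 5345 and 3295 in replicates 2. Their control tags per M were 99.0 and 123 in replicates 1, and 1131 and 785 in replicates 2. The split of replicates 1 against replicates 2 held 3196 regions and the crossed split 2489. A link between same-numbered libraries was therefore not excluded. With the replicate number as a block, input calls were 50 and 49, enrichment calls 0 and IP calls 190 (112 higher and 78 lower, against 39 and 11 without the block). Alternatives on strand and on gene lists were not run.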

Other observations

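The thinning, strong-region, RNA-level and locus tests were chosen after the counts of regions called at one age only were seen; the bounds for thinning and RNA level were set before the results of those tests.

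A few places held large stacks of tags in some libraries. On chromosome 2, peaks from 98502431 to 98507347 (mm9) held 402 and 368 IP tags per M at 2 weeks (10 and 8 peaks), 6.70 in 6-week replicate 1 (3 peaks) and 1831 in 6-week replicate 2 (13 peaks). The controls stacked there too, with 89.3 and 70.5 tags per M at 2 weeks and 1.52 and 339 at 6 weeks. A peak on chromosome 8 from 3754400 to 3754500 held 1889 IP and 267 control tags per M in 6-week replicate 2 and was called in no other list. The mitochondrial chromosome had 2 and 12 peaks in the 2-week libraries and 1 and 15 in the 6-week libraries, so replicates 2 of both ages had more. Chromosome 19 from 5801183 to 5892777, which holds both regions named above whose input rose, had 701 and 1198 IP tags per M at 2 weeks (12 and 9 peaks) and 3153 and 2845 at 6 weeks (10 and 13 peaks). Its control tags were 175 and 217 per M at 2 weeks and 934 and 474 at 6 weeks.

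More regions were called at 2 weeks only than at 6 weeks only (4527 against 1359), and the deeper 2-week libraries may account for part of it: after thinning to equal depth the median ratio was 1.38, which met the bound of 1.5 set before the test. That result is left open because of a condition added afterwards: thinning only removes peaks and left the 2-week lists shorter (27782 peaks on average) than the 6-week lists (32845). Some regions had peaks that stayed at least 6-fold with a p under 1e-08 at the smallest depth. Of these, 248 were called at 2 weeks only and 89 at 6 weeks only, a ratio of 2.79 (exact 95% interval 2.18 to 3.59, counting error only). Only the called peaks were held to that depth. Absence at the other age was taken from the full lists, which were shallower at 6 weeks, so this ratio cannot decide on depth. The 248 and 89 regions are 5.48% of the regions called at 2 weeks only and 6.55% of those called at 6 weeks only. Depth stays open for them and for the rest. Lower agreement between the 6-week replicates (47.1% against 61.5%) and age itself stay open and were not tested.

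A hypothesis for regions called at one age only is that the RNA level of the locus differed, so that a site could be called only where its transcript was abundant. Jointly called regions within 10 kb of 2-week regions and of no 6-week region (813) had a median input log2 change of -0.13, and those near 6-week regions and no 2-week region (418) 0.07. The difference of -0.20 (bootstrap 95% interval -0.30 to -0.07; two-sided permutation p = 0.00284 over regions, which are not independent replicates) had the direction this explanation needs, but fell short of the 0.5 set before the test. The median IP change was 0.05 and 0.06 in these sets, the median enrichment change 0.08 and -0.04, and input calls were 8 higher and 7 lower near 2-week regions and 6 and 4 near 6-week regions. The median shift is small against the spread between regions (quartiles -0.69 and 0.40 near 2-week regions), so RNA level as the cause for single regions cannot be told apart from a change in m6A or from sampling. Of the 4527 2-week regions, 883 had any jointly called region within 10 kb. That count includes neighbours also near a 6-week region, which were left out of the 813.

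Where a locus held several regions called at one age only, they tended to be of one kind. Of 962 loci with at least 2 such regions, 244 held both kinds, against a median of 400 and a lowest value of 340 when the kinds were permuted over the regions (permutation p = 1e-05, the smallest that 100000 permutations can give). Changes that act on a whole locus may give such a pattern, but neighbouring regions are not independent, and the test does not say what changed.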
